A study of Rattus norvegicus with 59 samples.

How the data were processed

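Nuclei were taken from the left ventricle of male Sprague Dawley rats and sorted on PCM1, a centriolar satellite protein that marks the nuclei of cardiomyocytes, per the labels. In the surgery experiment, rats of about 170 g had the ascending aorta banded for 6 weeks, and sham-operated rats had the operation without tightening of the suture. Banded rats were kept only if the heart was hypertrophied and not failing, per the labels. In the exercise experiment, rats of about 280 g were trained on a treadmill for 6 weeks and were compared with untrained controls. Each of these 4 groups had 4 RNA libraries of PCM1-positive nuclei with count columns (the control group had 5 such RNA samples, of which control 5 had no count column) and 4 samples for chromatin immunoprecipitation of each of H3K9me2 and H3K27me3, histone marks associated with gene repression. The series held 59 samples. Of these, 16 RNA libraries had count columns of their own, and the other 43 samples (the chromatin samples, 4 inputs and the RNA fractions) had none among the files used here. The labels do not state in words that each replicate is a separate animal, so p-values measure the spread between these samples, which may be partly technical.

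For RNA, the authors deposited raw read counts per gene as whole numbers, per the file headers and values. The smallest stored count was 1 in every library, so that a gene without reads cannot be told from a gene with a single count, and low folds are compressed. In the exercise table, 2 rows without a gene name repeated the column totals exactly (largest difference 0%) and were left out. The submitters' processing notes name Bowtie, SAMtools, R 2.15.1 and edgeR without their roles. The aligner settings, the counting rule, the use of strand and the genome build are not given in the sources used here, so genes that overlap or share reads with near copies are uncertain. The authors also deposited log2 RPM values per gene as 1 column per group with a false discovery rate (a p-value adjusted for many tests), and a table of log2 fold changes and false discovery rates between PCM1-positive and PCM1-negative nuclei. How the libraries of a group were combined and which test gave those rates is not stated in the file headers. For chromatin, the authors deposited log2 RPM per genomic bin, again as 1 column per group. The bins came from circular binary segmentation, per the file names. Which samples set the bin borders is not given in the sources used here, so the bins may not be independent of the groups compared. The columns of a mark had nearly equal totals, about 0.967 M RPM each, so a change of a mark over the whole genome would not show in these values.

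Gene IDs were used as given. None of the 22938 IDs of the count tables (0 matched) could be paired with a gene name, since the reference gene table used here, with 47357 genes of assembly GRCr8, carried 0 Ensembl IDs. For this reason the gene lists and cell type markers chosen in advance, which were written as gene names, were not tested, and at most 2 IDs per direction are printed for each comparison. The relation between marks and RNA was not computed, because genes could not be placed on the bins. Contrasts that use ungated nuclei or whole tissue were not analysed here.

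Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Surgery and exercise libraries were fitted separately, and the difference between both effects was tested in a fit of all 4 groups. SEs were derived from the F statistic. DESeq2 1.42.0 and limma 3.58.1 (voom, camera, fry) served as alternatives and for lists of genes. Chromatin values were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

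The comparisons, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. The fixed design compared 4 sham with 4 banded libraries. Sham replicates 2 and 3 were then found to differ by little more than counting error: over 10876 genes, the squared difference divided by its counting variance averaged 1.27 (1 for counting error alone), against 6.06 to 84.8 in the other 23 pairs of libraries within a group. For genes with 21 to 750 summed counts the mean was 1.07, against 2.70 to 28.2. A small difference beyond counting error remained, carried by abundant genes, of which 5 had a ratio above 50. Because the pair came so close to the noise of sampling, their counts were added and used as 1 sample, which departs from the fixed design and was decided after the data were seen. The surgery comparison therefore had 3 sham and 4 banded samples, and values with the pair kept apart are given beside the results for which they were computed. When the counts were added, 1 was taken off to keep the smallest stored count at 1.

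Replicate numbers are shared between groups in the labels. The deviations of same-numbered libraries from their group means correlated at 0.0905 to 0.749 in the surgery experiment over genes averaging more than 1 CPM, at 0.106 to 0.768 over genes averaging more than 5 CPM, and at -0.0161 to 0.140 and -0.0312 to 0.120 in the exercise experiment. The surgery values lay on either side of the fixed limit of 0.1 depending on the genes used, at most 1 number was the best match both ways, and 2 of the sham libraries counted as 1 sample. Whether the surgery numbers pair the animals was therefore left open, no block was used, and the blocked value is given where it changes a call. The exercise numbers were not taken to pair the animals.

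The rule for naming genes asked for genes with a name, past the threshold, with groups that do not overlap and an average log2 CPM of at least 3. Without gene names it could not be applied in full, so the IDs with the smallest p among genes above that level, at most 2 per direction and comparison, were taken instead, a choice made after the data were seen. ENSRNOG00000008356 in the difference between effects (below that level in the fit of all groups) and ENSRNOG00000015642 were also chosen after their values were seen. For chromatin, the fixed test needed a value per library, and with 1 column per group no test was possible. A difference of more than 0.5 on the log2 scale was used as a rule of size instead, chosen after the values were seen, with no added pseudocount, and the 4 bins with the largest difference in each direction were listed in the results, of which the largest are printed. The direction of the authors' PCM1 table was settled from the data: over 12848 genes, the excess of control replicate 1 over the table's average level had a Spearman rho of -0.826 with the table's log2 fold change, so negative values were read as higher in PCM1-positive nuclei. This goes against the name of the table, which puts PCM1-positive first, and each list and share of PCM1-enriched genes rests on it. Lists of genes more than 2-fold and more than 8-fold enriched in either fraction were drawn from that table after the data were seen. Control replicate 1 is among the animals whose fractions were sequenced, per the labels, so these lists may not be independent of the control group. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry.

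The edgeR procedure was tested on simulated data with 200 changed genes. For the surgery design (12689 genes), 10% of 100 genes with a true fold of 2 and 75% of 100 with a fold of 4 were called, with 6 false calls. For the exercise design (10815 genes), the shares were 59% and 99%, with 9 false calls. The simulation drew each gene independently and left out any structure that genes share across libraries. These shares and false calls may therefore not hold for the real libraries. Alternatives covered other normalizations, count filters, tools, a replicate block, all groups in 1 fit, each replicate left out, pseudocounts and median centring. Those added after the data were seen were an estimated correlation for the lists under each alternative, the subtraction of 1 from every count, a covariate for the share of PCM1-negative-enriched genes, DESeq2 without a count filter, DESeq2 and voom with the sham pair kept apart, fits without sham 1 and banded 1 or without the sham pair, a false discovery rate of 0.01 or a fold over 2 in the PCM1 table, the share of counts with the sham pair kept apart, and a bin difference over 1. Total counts per library ran from 1.82 M to 14.4 M. Intervals on shares of counts are exact binomial 95% intervals and cover counting error only, since PCR copies are not independent molecules.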

Results

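The series asked how pathological and physiological growth of the heart differ in the chromatin and RNA of cardiomyocyte nuclei, with H3K9 methylation named in its title. Nuclear RNA was counted in 16 libraries of PCM1-positive nuclei from 4 groups: sham-operated and aorta-banded rats, and control and treadmill-trained rats. Total counts were 3.18 to 14.1 M in the sham libraries, 2.58 to 14.4 M in the banded ones, 1.82 to 7.80 M in the control ones and 2.14 to 7.60 M in the trained ones. H3K9me2 and H3K27me3 were given as 1 value per group and bin, so their differences have no replicate check. Genes appear by their IDs, because the files pair no ID with a name.

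Sorting on PCM1 was meant to separate cardiomyocyte nuclei from those of other cells. In the authors' deposited table, 6635 of 12848 genes had a false discovery rate under 0.05 between the fractions, 3084 of them higher in PCM1-positive nuclei and 3551 higher in PCM1-negative nuclei. Among these, 604 genes were more than 8-fold higher in PCM1-positive and 1319 more than 8-fold higher in PCM1-negative nuclei. The lowest rates in the authors' deposited table belonged, on the PCM1-positive side, to ENSRNOG00000006204 (log2 fold change -5.38, PCM1-negative over PCM1-positive) and ENSRNOG00000014641 (-4.67), and on the PCM1-negative side to ENSRNOG00000020562 (5.39) and ENSRNOG00000020440 (5.57). In the 16 PCM1-positive libraries, the genes enriched more than 8-fold in PCM1-positive nuclei had a median of 6.73 log2 CPM, and those enriched more than 8-fold in PCM1-negative nuclei a median of 1.65 log2 CPM. The sign of the table was read from control replicate 1, which is among these libraries, so the order of these medians does not test the sort. The table's own average level also differed between these genes (median 6.43 and 4.30 log2 CPM). The table gave no values per library, so its fold changes carry no error here.

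The share of a library's counts that came from the 1319 PCM1-negative-enriched genes differed between libraries of the surgery experiment. It was 4.32% in sham replicate 1 (exact binomial 95% interval 4.31 to 4.33) and 4.45% in banded replicate 1 (4.44 to 4.46). In the other surgery libraries it lay between 0.658% and 1.68%. The group means were 2.19% ± 1.90 for sham (SD, n = 3, replicates 2 and 3 counted once) and 2.08% ± 1.62 for banded rats (SD, n = 4), a difference far smaller than the spread. With the sham pair kept apart the sham mean was 1.81% ± 1.73 (SD, n = 4), below the banded mean, and the banded library was higher in all 4 same-numbered pairs, by 0.108 to 0.656 percentage points. Control rats had 0.791% ± 0.200 and trained rats 0.712% ± 0.123 (SD, n = 4 each).

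**Figure D1:**
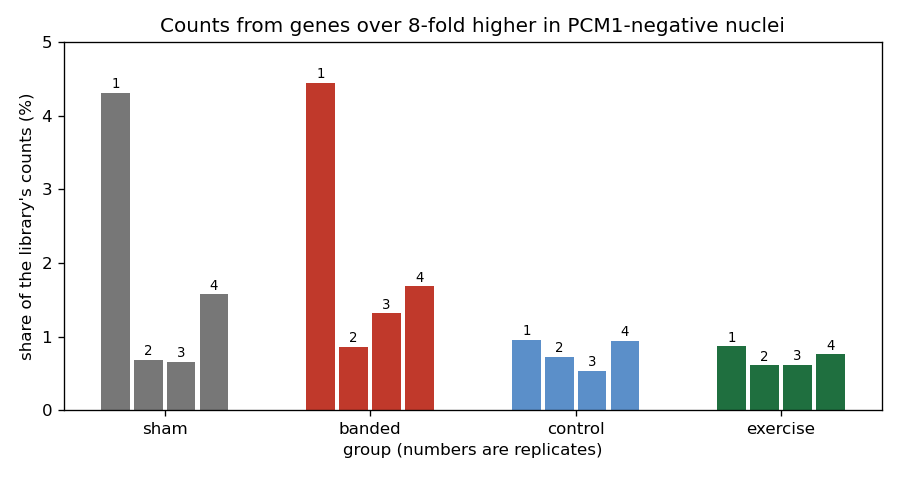
Share of each library's counts, in percent, from the 1319 genes more than 8-fold higher in PCM1-negative nuclei, by group, with 1 bar per library and the replicate number above it. Sham replicate 1 (4.32%) and banded replicate 1 (4.45%) stand above the other libraries, the highest of which is at 1.68%.

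Sham replicates 2 and 3 differed by little more than sampling noise and were counted as 1 sample. The squared difference of their counts averaged 1.07 times the counting variance over genes with 21 to 750 summed counts, while the other 23 pairs of libraries of a group averaged 2.70 to 28.2 times. Over all 10876 genes compared the ratio was 1.27, so a small difference beyond sampling remained.

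**Figure D2:**
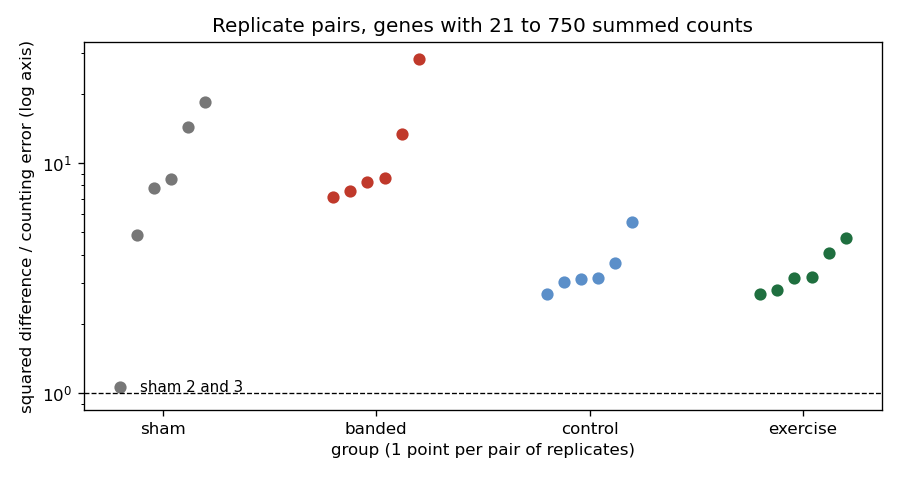
Squared count difference divided by counting variance, averaged over genes with 21 to 750 summed counts, on a log axis, for each pair of replicates within a group. The dashed line at 1 marks counting error alone. The pair of sham replicates 2 and 3 lies at 1.07 and the next lowest pair at 2.70.

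Banded and sham rats were compared to ask what pressure overload changes in cardiomyocyte nuclear RNA. ENSRNOG00000008356 was the 1 gene of 12689 tested that passed the threshold. It fell by 5.80 on the log2 scale (SE 0.48, edgeR quasi-likelihood test, adjusted p = 0.0178), from 26.4 ± 6.19 CPM in sham rats (SD, n = 3) to 0.535 ± 0.388 CPM in banded rats (SD, n = 4). Every control library held the stored minimum of 1 count (0.287 ± 0.185 CPM), and the trained libraries held 1 to 4 counts (0.469 ± 0.348 CPM, SD, n = 4 each). At such counts the CPM values and their SDs largely follow library size and do not measure a level of the gene. The sham libraries alone were far above the stored minimum. Counts were 113 to 327 in the sham and 2 to 10 in the banded libraries, so the fold depends on the prior count and is imprecise. No gene passed as higher in banded rats (0 in edgeR). DESeq2 called 0 higher and 2 lower, voom called 0 genes, and 234 genes had an unadjusted p under 0.05 in edgeR. With the sham pair kept apart that number was 420, and 792 with the replicate number as a block as well. With no effect, a share of 0.05 of the genes tested would be reached by chance. The 234 and the 420 lie below that share, so they are no sign of changed genes, while the 792 lie above it. Of genes that did not pass, ENSRNOG00000026472 was at 36.6 ± 4.41 CPM in banded and 85.9 ± 19.0 CPM in sham rats. ENSRNOG00000019914 was at 51.4 ± 14.8 CPM against 19.5 ± 6.48 CPM, and ENSRNOG00000020807 at 43.9 ± 9.73 CPM against 23.0 ± 4.92 CPM (adjusted p = 1.00 for each, edgeR). With sham replicates 2 and 3 kept apart, edgeR called 0 genes higher and 1 lower and DESeq2 12 higher and 4 lower. The call of ENSRNOG00000008356 was lost in edgeR without sham replicate 4 (adjusted p = 0.119), banded replicate 2 (0.0885), banded replicate 3 (0.222) or banded replicate 4 (0.109), and its fold lay between -6.47 and -5.48 over all libraries left out in turn. The call was also lost without sham replicates 2 and 3 together, which are 1 sample in the fit (edgeR adjusted p = 0.0555).

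Genes enriched in either fraction showed no shift with banding that passed the test. The 2468 PCM1-positive-enriched genes had a median log2 fold change of 0.0033 and the 2878 PCM1-negative-enriched genes one of -0.016 (camera adjusted p = 0.760 and 0.395). The mean of the PCM1-negative-enriched genes was 0.012 and camera's direction upward, against the sign of the median. With an estimated correlation (0.403 and 0.567) the adjusted p was 0.963 for both. The direction of the PCM1-negative-enriched list depended on the libraries: its median was 0.52 without sham replicate 1 (adjusted p = 1.58e-25) and -0.37 without banded replicate 1 (adjusted p = 6.74e-08). It was 0.14 without banded replicate 2 (4.79e-08), 0.041 without banded replicate 3 (0.00994) and 0.11 with the sham pair kept apart (8.92e-07). The median of the PCM1-positive-enriched list was -0.13 without sham replicate 1 (1.81e-10), 0.10 without banded replicate 1 (1.82e-07) and -0.042 without banded replicate 2 (0.0364). These p-values assume a correlation of 0.01 between genes. With an estimated correlation none of the 17 alternatives gave an adjusted p under 0.05 for either list (lowest 0.142 for the PCM1-negative-enriched and 0.0964 for the PCM1-positive-enriched genes). With the preset correlation, 28 of the 34 other splits of the same samples gave the PCM1-negative-enriched list an unadjusted p under 0.05 (lowest 6.21e-99). With the replicate number as a block and the sham pair kept apart, the medians were -0.043 for the PCM1-positive-enriched and 0.15 for the PCM1-negative-enriched genes (camera adjusted p = 0.00811 and 7.30e-12, and 0.0964 and 0.142 with an estimated correlation).

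Training was compared with control to follow physiological growth. No gene passed the threshold (0 of 10815 in edgeR, lowest adjusted p = 0.0709), while 761 genes had an unadjusted p under 0.05. That exceeds the share of 0.05 of genes tested that no effect would give. However, 7 of the 35 splits of the samples, the real one included, reached as many. Voom called 0 genes. DESeq2 called 25 higher and 12 lower with the count filter and 0 without it. The lowest p belonged to ENSRNOG00000013409, at 15.0 ± 1.50 CPM in trained and 31.6 ± 2.81 CPM in control rats (SD, n = 4 each, log2 fold change -1.02, SE 0.13, edgeR adjusted p = 0.0709). ENSRNOG00000009715 was at 112 ± 6.78 CPM against 181 ± 22.1 CPM (log2 fold change -0.66). ENSRNOG00000004198 was at 586 ± 58.2 CPM in trained rats and 355 ± 43.2 CPM in controls (0.76), and ENSRNOG00000025110 at 31.9 ± 5.44 CPM and 18.2 ± 1.32 CPM (0.84). For these 3 genes the adjusted p was 0.158. In all 4 genes the trained and control libraries did not overlap, as did 4.15% of all genes tested, where chance gives 2.86%. The 2434 PCM1-positive-enriched genes had a median log2 fold change of 0.033 and the 1987 PCM1-negative-enriched genes one of -0.072 (camera adjusted p = 0.0585 for both). With an estimated correlation the adjusted p was 0.329 and 0.584. Without control replicate 3 the lists passed (adjusted p = 0.00248 and 1.10e-05), as they did without exercise replicate 1 (0.0111 and 0.000561). With an estimated correlation the adjusted p was 0.0736 and 0.146 without control replicate 3, and 0.228 and 0.271 without exercise replicate 1.

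The authors' deposited tables list more genes. In the authors' deposited table for surgery, 604 genes had a false discovery rate under 0.05, 335 higher and 269 lower in banded rats. In the authors' deposited table for exercise there were 291, 146 higher and 145 lower in trained rats. From the counts, 116 of the 604 and 152 of the 291 had an unadjusted p under 0.05 in edgeR, and 1 and 0 of them passed the adjusted threshold. For surgery, the values from the counts use sham replicates 2 and 3 as 1 sample and were not computed with the pair kept apart. Over all genes tested, 420 had an unadjusted p under 0.05 with the pair kept apart and 234 with it counted once. The groups did not overlap in 95 of the 604 (15.7%) and in 76 of the 291 (26.1%), against 3.20% and 4.15% of all genes tested and 5.71% and 2.86% by chance. The listed genes were chosen by the authors for a difference in these same libraries, so a share above chance is not independent evidence. The authors' group values differed by less than 0.5 on the log2 scale for 352 and 193 of these genes.

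The effects of banding and of training were then compared with each other. ENSRNOG00000008356 was the 1 gene of 12650 whose banding effect differed from its training effect (difference -6.64 on the log2 scale, SE 0.94, edgeR adjusted p = 0.0408), and 488 genes had an unadjusted p under 0.05. The 488 lie below a share of 0.05 of the genes tested, which no effect would give, so they are no sign of further differences. DESeq2 called 2 higher and 2 lower and voom called 0 genes. The call was lost when any of 13 of the 16 libraries was left out, and held without sham replicate 2, sham replicate 3 or banded replicate 1 (adjusted p 0.00808 to 0.491 over the 16 libraries), while the difference stayed between -7.32 and -6.30. Leaving out sham replicate 2 or 3 alone kept the other in its place, so no sample was removed. Without both, the call was lost (edgeR adjusted p = 0.0725). Every control library held the stored minimum of 1 count for this gene, so its training effect has no measured baseline. With 1 subtracted from every count, the difference was -9.99 and the edgeR adjusted p 0.911. With the replicate number as a block and the sham pair kept apart no gene passed (0 in edgeR, 861 at an unadjusted p under 0.05; difference -6.60 and adjusted p = 0.176 for this gene). The gene was chosen after its values were seen. ENSRNOG00000004078 was lower in banded than sham rats (30.1 ± 2.89 against 56.7 ± 9.50 CPM) and higher in trained than control rats (94.4 ± 30.3 against 66.0 ± 5.77 CPM), without passing (edgeR adjusted p = 0.369). Across the 10800 genes tested in both, the fold changes of banding and training had a Pearson r of -0.0272 and a Spearman rho of -0.0150. Genes are not independent, and 90 of 100 drawn relabellings gave an r at least as far from 0 (96 of 100 for rho). The 2480 PCM1-positive-enriched genes had a median difference of -0.043 and the 2830 PCM1-negative-enriched genes one of 0.050 (camera adjusted p = 0.280 and 0.0842, and 0.818 for both with an estimated correlation). The PCM1-negative-enriched median was 0.61 without sham replicate 1 and -0.31 without banded replicate 1 (camera adjusted p = 1.14e-19 and 0.00146, and 0.133 and 0.564 with an estimated correlation). It also passed with the preset correlation without banded replicate 2, 3 or 4, control replicate 3 or exercise replicate 1 (medians 0.10 to 0.22). The PCM1-positive-enriched median was -0.17 without sham replicate 1, 0.057 without banded replicate 1, -0.082 without banded replicate 2 and -0.083 without banded replicate 3. None of these calls held with an estimated correlation. With the replicate number as a block and the sham pair kept apart, the medians were -0.086 for the PCM1-positive-enriched and 0.19 for the PCM1-negative-enriched genes (camera adjusted p = 0.00105 and 4.14e-10), and with an estimated correlation the adjusted p was 0.0271 and 0.0602. In the authors' deposited tables, 19 genes were higher in both and 19 lower in both (4.53 and 3.61 for independent lists), while 21 were higher with banding and lower with training and 28 the reverse (4.50 and 3.64). The values for independent lists were taken over the 10800 genes tested in both fits here. Same and opposite directions alike exceeded them, so the overlap shows neither a shared nor an opposed response, and its cause was not tested.

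H3K9me2 was compared over 6171 bins covering 2532 Mb of 20 chromosomes, in the coordinates of the files, whose genome build is not given in the sources used here. Between banded and sham rats, 9 bins differed by more than 0.5 on the log2 scale, 2 higher and 7 lower in banded rats (SD over bins 0.154). With a pseudocount equal to the 10th percentile, 1 bin was higher and 0 were lower, and 0 bins differed by more than 1. The largest gain lay on chromosome 5 from 133955001 to 134525001 (7.20 log2 RPM in banded, 6.44 in sham, difference 0.76). The largest loss lay on chromosome 1 from 245415001 to 245635001 (6.36 and 6.93, difference -0.57). Between trained and control rats, 3 bins differed by more than 0.5, all lower in trained rats (SD over bins 0.0981), and 1 differed by more than 1. The largest was the same chromosome 5 segment (3.79 log2 RPM in trained, 5.42 in control rats, difference -1.63), followed by chromosome 15 from 29065001 to 29425001 (5.64 and 6.45, difference -0.81). Sham rats differed from control rats in many more bins, 1642 (26.6%), and these groups also differed in start weight, surgery and experiment.

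H3K27me3 was compared over 9703 bins covering 2510 Mb. Between banded and sham rats, 4 bins differed by more than 0.5, 2 in each direction (SD over bins 0.117), and 1 in each direction with a pseudocount equal to the 10th percentile, while 0 differed by more than 1. The largest gain lay on chromosome 8 from 36235000 to 36525002 (6.34 log2 RPM in banded, 5.64 in sham, difference 0.70) and the largest loss on chromosome 7 from 105735000 to 105845002 (4.98 and 5.80, difference -0.82). Between trained and control rats, 12 bins differed by more than 0.5, 8 higher and 4 lower in trained rats (SD over bins 0.109). With a pseudocount equal to the 10th percentile, 0 bins were higher and 1 was lower, and without the lowest 10% of bins 3 were higher and 3 lower. At a difference over 1, 1 bin was lower. The largest loss lay on chromosome 5 from 133995000 to 134525002 (3.43 log2 RPM in trained, 4.72 in control rats, difference -1.28), inside the segment named for H3K9me2, and the largest gain on chromosome 4 from 101395000 to 101525002 (3.25 and 2.51, difference 0.75). Sham and control rats differed in 305 bins.

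**Figure D3:**
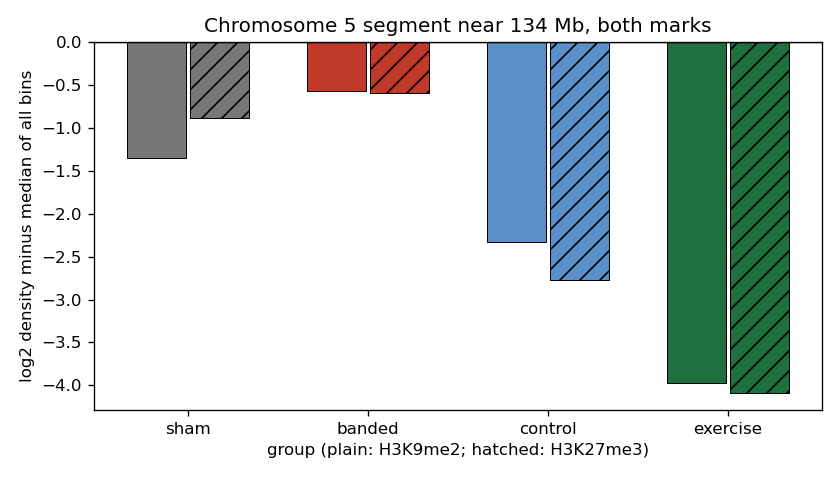
Log2 density of H3K9me2 (plain bars) and H3K27me3 (hatched bars) in the chromosome 5 segment, minus the median over all bins of the group, for the 4 groups. Both marks are lowest in trained rats (-3.98 and -4.09) and nearest to the median in banded rats (-0.57 and -0.59).

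Across bins, the differences of banding and of training ran in opposite directions for H3K9me2 (Spearman rho -0.511, and -0.676 to -0.406 within the 20 chromosomes) and in the same direction for H3K27me3 (rho 0.489, and 0.312 to 0.599). Against the H3K9me2 density of control rats, the H3K9me2 differences had a rho of 0.553 for banded minus sham and -0.541 for trained minus control. Against the density of its own reference group, each had a negative Pearson r (-0.193 for banded minus sham with sham, -0.484 for trained minus control with control), and a difference shares its reference values, which by itself pulls the correlation down. The SD of H3K9me2 density over bins was 0.288 in sham, 0.299 in banded, 0.482 in control and 0.443 in trained rats. Bins are not independent replicates, and each group is 1 pooled value, so these correlations describe these pools. The H3K9me2 and H3K27me3 densities of a group correlated over 6156 bins with a rho of 0.162 in sham, 0.327 in banded, 0.795 in control and 0.799 in trained rats. No input was subtracted here, so background shared by both marks may raise these values. Both this rho and the SD of H3K9me2 density differed more between the experiments than within them, and the cause was not tested.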

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

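The tests of the sham pair, of the share of PCM1-negative-enriched genes and of ENSRNOG00000015642 in this part were chosen after the results were seen, and the limits set for the splits were written down after the counts were known.

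ENSRNOG00000008356 stands out because its banding effect differed from its training effect, by -6.64 on the log2 scale (edgeR adjusted p = 0.0408). Sham libraries had 22.5 to 35.5 CPM and the other 12 libraries at most 0.953 CPM. Every control library held the stored minimum of 1 count, so the training effect of this gene has no measured baseline. With 1 subtracted from every count, the difference was -9.99 and the edgeR adjusted p 0.911. With the replicate number as a block and the sham pair kept apart, its adjusted p was 0.176 and its difference -6.60, about as large as without the block. Of 100 drawn pairs of splits of the samples, the real one included, 6 gave at least 1 gene (highest other 99), so chance could not be excluded for the count of 1 in the difference. For banding alone, 1 of the 35 splits of the 7 samples gave as many genes, the real one (1 gene, highest other 0). This is the lowest share the test can reach and sets 1 call against 0, so by itself it does not exclude chance. The count rests on 1 gene, whose call was lost in edgeR without sham replicate 4, banded replicate 2, banded replicate 3 or banded replicate 4 (adjusted p = 0.119, 0.0885, 0.222 and 0.109). The call was also lost without sham replicates 2 and 3 together (edgeR adjusted p = 0.0555). At an unadjusted p under 0.05, however, other splits reached 3505 genes against 234 in the real one, and 22 of 35 reached as many, which points to a structure of the samples apart from the surgery. These splits took no account of the replicate numbers, whose pairing was left open: with the sham pair kept apart, 792 genes had an unadjusted p under 0.05 with the replicate number as a block and 420 without it. For training, all 35 splits gave at least the 0 genes of the real split (highest other 6). With a real count of 0 no other outcome was possible, so the count of calls decides nothing about chance. At an unadjusted p under 0.05 the real split gave 761 genes. As many were reached by 7 of the 35 splits, the real one included (highest other 1084), so chance could not be excluded.

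ENSRNOG00000015642, chosen after its values were seen, was at 3915 CPM in banded replicate 3, far from the other 3 banded libraries (group mean 2265 ± 1111 CPM, SD, n = 4). The mean was 789 ± 166 CPM in sham rats (SD, n = 3), 2757 ± 992 CPM in control rats (highest library 3882 CPM) and 2102 ± 700.4 CPM in trained rats (SD, n = 4 each). This was the 1 sample so far from its group among 48 groups of values examined, where chance gives about 2.4.

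Sham replicates 2 and 3 differed by little more than counting error. Shallow sequencing may hide differences between libraries, but with all libraries thinned to 1 depth the lowest ratio among the other pairs was still 4.19, which argues against it. A candidate explanation that stays open is that both libraries came from 1 animal or RNA pool: their ratio was 1.07 for genes with 21 to 750 counts. The labels name them as separate samples, and no biological explanation was tested.

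Genes enriched in PCM1-negative nuclei were high in sham replicate 1 and banded replicate 1. Sequencing depth does not account for this, as the lowest share among libraries at least as deep as banded replicate 1 was 0.859%. Banding does not account for the whole pattern, as sham replicate 1 was at 4.32%, above banded replicates 2, 3 and 4. Whether banding had a smaller effect stays open. The banded library was higher in all 4 same-numbered pairs (by 0.108 to 0.656 percentage points). These pairs use sham replicates 2 and 3 as separate samples, and whether the numbers pair the animals was left open. With replicates 2 and 3 counted once, the mean was 2.19% in sham and 2.08% in banded rats. A candidate source is nuclei or free RNA of PCM1-negative cells carried through the sort. At least 98.9% of the 1181 such genes measured were above the mean of the other samples of the group in both libraries. The median was 3.86-fold in sham and 3.30-fold in banded, against 1.10-fold and 1.12-fold over all genes. The libraries were singled out by these same genes, so the values show that the rise was broad among them and do not test its source. The cell types behind them were not examined.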

How the results depend on the processing

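Alternatives chosen after the data were seen are the tests of both enriched gene lists (also with an estimated correlation), the fits without sham 1 and banded 1 or without sham 2 and sham 3, DESeq2 and voom with the sham pair kept apart, DESeq2 without a count filter, the subtraction of 1, the covariate, a rate under 0.01 or a fold over 2 in the PCM1 table, the share of counts with the sham pair kept apart, and a bin difference over 1. For banded against sham (1 gene), the count was 0 with library size only, with limma-voom and without sham 2 and sham 3, 2 with DESeq2, and 16 with DESeq2 with the pair kept apart. It was 1 under the other 12 settings. Leaving out 1 replicate gave 0 to 1. For training (0 genes), DESeq2 gave 37 with the count filter and 0 without it, 1 replicate left out gave 0 to 1 (1 without control replicate 2), and all other settings gave 0. For the difference of effects (1 gene), the count was 0 with library size only, limma-voom, limma-voom with the pair kept apart, 1 subtracted, the covariate, and without sham 2 and sham 3, 4 with DESeq2 and 10 with DESeq2 with the pair kept apart, and 0 to 1 with 1 replicate left out. DESeq2 without a count filter gave 1 for both surgery results. The cause was not tested.

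With the replicate number as a block (replicate block, sham pair kept apart) the count was 1 for banding, 0 for training and 0 for the difference, against 1, 0 and 1 without a block. The block also gave the PCM1-positive and PCM1-negative lists medians of -0.043 and 0.15 with banding, 0.029 and -0.056 with training and -0.086 and 0.19 for the difference, all past the threshold with the preset correlation. With an estimated correlation, of these only the PCM1-positive list in the difference passed (adjusted p = 0.0271). The surgery correlations fell on both sides of the limit and at most 1 number matched best both ways, so whether the surgery numbers pair the samples was left open. For H3K9me2, H3K27me3 and the PCM1 table, unlike the RNA counts, no paired analysis was possible because each group has 1 value.

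For the PCM1-negative-enriched list, the median log2 fold change with banding was 0.11 with the pair kept apart, 0.12 without sham 1 and banded 1 and -0.27 without sham 2 and sham 3 (adjusted p = 8.92e-07, 2.72e-05 and 2.37e-14), and -0.37 to 0.52 with 1 replicate left out (reversed to -0.37 without banded replicate 1). For the PCM1-positive-enriched list it was -0.076 without a count filter, -0.026 without sham 1 and banded 1 and 0.12 without sham 2 and sham 3, and -0.13 to 0.10 with 1 replicate left out (-0.13 without sham replicate 1, -0.042 without banded replicate 2). With training, the PCM1-positive list passed at 0.044 without a count filter and 0.027 with a minimum count of 50, and the PCM1-negative list at -0.072 with that minimum. With 1 replicate left out they ran from 0.013 to 0.056 and from -0.14 to -0.019. For the difference of effects, the PCM1-negative list was 0.16 with the pair kept apart, 0.20 without sham 1 and banded 1 and -0.19 without sham 2 and sham 3, and -0.31 to 0.61 with 1 replicate left out (-0.31 without banded replicate 1). The PCM1-positive list was -0.086, -0.066 and 0.088 in these fits, -0.10 without a count filter, and -0.17 to 0.057 with 1 replicate left out (0.057 without banded replicate 1). With banding and 1 replicate left out, the adjusted p of the PCM1-negative list ranged from 1.58e-25 to 0.971. Apart from the block, no list passed under any alternative with an estimated correlation. The cause of these shifts was not tested. The correlation of fold changes stayed between -0.133 and 0.0449, and the PCM1 table kept 5516 genes at a rate under 0.01 and 5559 with a fold over 2.

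Bins past 0.5 numbered 1 for H3K9me2 with banding, 2 for H3K27me3 with banding and 1 for H3K27me3 with training under a pseudocount equal to the 10th percentile, and 6 for H3K27me3 with training without the lowest 10% of bins. At a difference over 1 they numbered 0, 1, 0 and 1 for H3K9me2 with banding and training and H3K27me3 with banding and training. Library depth limits low genes: the smallest library held 1.82 M counts. Not run were limma-trend on the deposited RPM, which has group values only, the replicate tests of chromatin, the other alternatives of the PCM1 table, the fraction contrasts, the relation of marks to RNA, and the gene lists and markers written as names.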

Other observations

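All tests in this part were chosen after the results were seen.

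In the chromosome 5 segment from 133955001 to 134525001 both marks were lower in trained than in control rats, by -1.63 for H3K9me2 and -1.28 for H3K27me3 on the log2 scale. A change in H3K9me2 alone is argued against by the H3K27me3 difference of -1.28. The segment was chosen as the largest fall of H3K9me2 among all 6171 bins, so no other bin could fall further. None of the 1969 other H3K9me2 bins with no more signal in control rats differed by more than 0.57, however. That gap makes noise of bins with little signal less likely without excluding it. A different copy number of the segment in the animals pooled for a group is a possible explanation, as the 3 bins on either side differed by at most 0.23 in either mark. It cannot be told apart from a loss of both marks. Banded minus trained was nearly alike in both marks (3.41 for H3K9me2 and 3.52 for H3K27me3). Less alike were banded minus sham (0.76 and 0.33) and sham minus control (1.01 and 1.90, the largest gap at 0.89). The inputs, which would decide the question, were not analysed here. The segment also differed between sham and control rats, neither banded nor trained, so its level does not follow training alone.

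Some genes had all samples of 1 group above, or all below, the samples of the other 3 groups. Among 12650 genes there were 17 above and 29 below for sham (55.6 by chance if samples were exchangeable), 36 and 39 for banded (18.5 by chance), 41 and 45 for control (18.5) and 15 and 60 for trained rats (18.5). The experiments differ in start weight and handling, so samples are not exchangeable across them and these chance values are a rough guide.

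The differences of the 2 marks across bins went together for banding (Spearman rho 0.505, 6156 bins) and in opposite directions for training (rho -0.440). On chromosome 4 from 101395001 to 101525001, trained minus control was -0.57 for H3K9me2 and 0.75 for H3K27me3. The H3K27me3 signal there was low, 2.51 log2 RPM in control rats, where the lowest value of any bin was 1.70. With a pseudocount equal to the 10th percentile, 0 H3K27me3 bins were higher in trained rats by more than 0.5. No explanation was tested.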
